A study of Drosophila melanogaster with 31 samples.

How the data were processed

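RNA-seq libraries built with an Illumina TruSeq kit from total RNA of male Drosophila melanogaster were available for antennae (8 libraries) and brains (23 libraries). The antennal libraries came from the 2nd and 3rd antennal segments of OreR, a wild-type strain, and of Orco2, a strain mutant for the odorant co-receptor gene Orco, and the brain libraries came from OreR. In each tissue, flies that had been exposed to odor and light were set against flies kept without these stimuli (0 min). Brains of HDAC6 mutants, which the series also describes, were not analysed here.

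The authors deposited 1 table per library with an estimated count and a TPM value (transcripts per 1000000) for each of 30490 transcripts, per the file headers. These values came from pseudoalignment with kallisto 0.43.1, per the submitters' processing notes, which also name CASAVA 1.7, edgeR 3.18.1 and the builds dm6 and GRCm38. The strand setting, the trimming and the release of the transcript annotation are not given in the sources used here. Estimated counts are not whole, because kallisto shares reads between transcripts, so genes with near-identical copies (Or19a and Or19b, AttA and AttB, the Hsp70 genes, LysB, LysD and LysE) and genes that overlap on either strand carry an uncertain split. The deposited TPM sums to 1000000 in each library and was used in 1 alternative only.

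Transcripts were assigned to genes with the Ensembl annotation of BDGP6.54, the source of all coordinates given here. Of the 30490 transcripts, 30255 matched, in 13821 genes. The remaining transcripts held 0.396% to 0.514% of the estimated counts of a library and were left out. Estimated counts were summed per gene and rounded to whole numbers. Totals ran from 18.5 to 76.7 M per library (median 31.1 M; M, 1000000 counts). Replicate libraries of 1 group differed by far more than sampling noise, so none was counted as a copy of another.

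Genes were tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr, robust fit), with 1 coefficient per group and no covariate, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. All 8 antennal libraries shared 1 fit (11298 genes tested) and all 23 brain libraries another (10431 genes tested), so that groups of 2 or 3 libraries shared an estimate of the spread. Adjusted p-values in the text come from this test unless another is named, and those of gene lists from limma, with adjustment over the lists of 1 comparison. Fold changes are log2 values with the standard error that the F-statistic implies, and levels are normalised counts per 1000000 (CPM), as mean ± SD over libraries. Where every library of a group had 0 counts, the fold is a lower bound against 3 counts over the group. The standard errors rest on the spread shared by all libraries of a fit. The series calls the replicates biological, but the labels do not say how many flies were pooled in each.

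The design, the 25 gene lists and the rule for the genes named were fixed before the data were examined. The rule took Orco first. For each pair of groups it took up to 10 genes per direction with the largest fold change among those with an adjusted p under 0.05, a mean log2 CPM of at least 1 and no overlap between the groups. It took up to 5 per direction for an interaction or a joint test, up to 4 members of each list with the smallest adjusted p, and, where no gene passed, the 5 genes with the smallest unadjusted p. Genes named outside it were chosen after their values were seen. The lists cover activity-regulated genes, odorant receptors, ionotropic receptors, odorant-binding proteins, perireceptor genes, Johnston's organ, heat shock, antimicrobial peptides, phototransduction, the circadian clock, synaptic vesicles, ion channels, neurotransmitter receptors, neuropeptides, oxidative phosphorylation, glycolysis, ribosomal proteins, the proteasome, chromatin regulators, glia, fat body, hemocytes, muscle, detoxification and oxidative stress. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation and with fry. Lists of midgut and testis genes were written after the data were seen.

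On simulated counts with known changes, the OreR stimulation contrast recovered 48% of 2-fold and 85% of 4-fold changes among 11017 genes. The genotype contrast at 0 min recovered 52% and 80% (11038 genes), 5-day brains at 30 min 33% and 83% (10364 genes), 10-day brains at 30 min 19% and 73% (10371 genes), and 25 against 5 days 32% and 75% (10372 genes). In the same order, 7, 6, 4, 4 and 5 unchanged genes passed. Camera at the preset correlation gave an unchanged list p = 0.0101 in the last case and p from 0.541 to 0.892 in the others. Counts were drawn independently around 1 mean per gene and tissue. They held no batch and no shift shared by many genes of 1 library, which the real libraries show. Recovery in the real data may therefore be lower.

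The alternatives planned at the start were DESeq2 size factors, the DESeq2 1.42.0 test, no filter on low counts, counts scaled from TPM, fits of the compared groups alone, the replicate letter as a block, and leaving out each library in turn. Each table holds a transcript length and an effective length, whose difference is the fragment length given to kallisto: 298, 301 or 354 bases for antennae and 325, 335 or 369 for brains. This value was used as a batch term, an alternative chosen after seeing the data. Other alternatives chosen after seeing the data were 1 to 3 surrogate variables (sva 3.50.0), limma voom with sample quality weights, effects averaged over groups, medians of lists relative to the 200 tested genes nearest in length to each member, the replicate letter as a block in the genotype contrasts, and fits without brain libraries that stood apart. Python 3.11.15, pandas 2.3.3 and numpy 2.4.6 were used to read the tables.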

Results

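Gene expression was compared between flies exposed to odor and light and flies kept without these stimuli, in antennae of OreR and Orco2 males aged 4 to 5 days (2 libraries per group) and in OreR brains. Brains of 5-day flies were taken at 0, 10, 20, 30 and 45 min (3 libraries per time), and brains of 10-day and 25-day flies at 0 and 30 min (2 libraries per group). The stimulated antennal libraries carry the times 10, 20 and 30 min in their label, so their exact duration is not known. Libraries held 18.5 to 54.9 M counts (M, 1000000) in antennae and 19.3 to 76.7 M in brains. In brains the fragment length given to kallisto partly followed time and age, so differences of either are partly confounded with it.

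Orco, which encodes the co-receptor that most odorant receptors need, was almost absent from Orco2 antennae, as the strain name implies. Antennae of the mutant also had fewer transcripts of many odorant receptors, among them Or47b, Or13a, Or46a and Or19a. They gained transcripts of cas, a zinc finger transcription factor gene of the embryonic nervous system, of Osi3, a gene of the Osiris family, and of ppk27, a gene of the pickpocket family of sodium channels. Orco stood at 8.06 ± 0.51 CPM in Orco2 and 1996 ± 8.60 CPM in OreR at 0 min (log2 -7.95 ± 0.13; adjusted p = 1.99e-06), and at 8.12 ± 0.66 and 2027 ± 18.6 CPM after stimulation (log2 -7.96 ± 0.13). At 0 min, 606 of 11298 genes passed (335 higher and 271 lower in Orco2), with 1843 at an unadjusted p under 0.05 where 565 would be expected by chance. With the fragment length as a batch term 1141 passed, with DESeq2 1093, with the compared libraries alone 311, and with a library left out 264 (Orco2 C), 267 (Orco2 B), 280 (OreR A) or 286 (OreR B). Genotype and strain background cannot be separated here, because each genotype is 1 strain.

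Among the genes higher in Orco2 at 0 min, CG42876 (11.9 CPM) and CG32640 (9.30 CPM) had no counts in OreR and were at least 169-fold and at least 133-fold higher (adjusted p = 0.00282 and 0.00789). cas rose to 39.4 ± 5.27 CPM from 0.0471 (log2 9.61 ± 0.42; adjusted p = 0.00018) and Osi3 to 72.1 ± 13.8 CPM (9.54 ± 0.78; adjusted p = 0.00151). The adjacent genes CG6912 and CG3984 were higher by 8.01 ± 0.47 and 6.55 ± 0.28, Uros2 by 7.45 ± 0.34 (188 ± 16.1 against 1.06 CPM), CG30428 by 7.20, ppk27 by 6.02 and CG42826 by 5.94. Among the genes lower in Orco2, Or19a had no counts against 7.82 ± 0.14 CPM in OreR (at least 220-fold; adjusted p = 0.00749), and Or46a stood at 0.0339 against 11.8 CPM (-8.70 ± 0.69; adjusted p = 0.00114). CG3397 was lower by a log2 of -7.59, sordd2 by -7.03 (0.956 against 107 CPM), CG17906 by -5.80 and CG3119 by -5.59. Or13a was at -5.56 ± 0.68 and its neighbor CG42766 at -5.33, so reads may be shared between these adjacent genes. Or47b, which detects fly-derived fatty acid methyl esters, fell to 1.72 ± 0.65 from 78.0 ± 12.2 CPM (-5.55 ± 0.33; adjusted p = 0.00038).

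The odorant receptor list lost transcripts as a group, while other chemosensory lists moved in both directions. Of 38 odorant receptors, 23 were lower at 0 min and none was higher (25 when adjusted over the list alone), with a median log2 change of -1.85. The list passed camera (adjusted p = 1.89e-45) but not with an estimated correlation (adjusted p = 0.314), and it passed fry (adjusted p = 0.0257). Of the receptors named above, Or46a is not in this list of antennal receptors. Besides those named above, Or19b was at -4.23 ± 0.30, Or69a at -4.20 ± 0.30, Or67b at -3.12, Or59b at -2.38 ± 0.19 (17.2 against 89.0 CPM), Or85f at -2.05 and Or22b at -1.82 ± 0.15. Among 17 ionotropic receptors, 5 passed (13 over the list alone): the co-receptor gene Ir25a (0.99 ± 0.10; 228 against 115 CPM; adjusted p = 0.0035), Ir75b (0.92) and Ir75c (0.90) were higher, and Ir76a (-1.02) and Ir93a (-1.23) lower. Among 24 odorant-binding protein genes, 5 passed (6 over the list alone), with Obp99d at -5.03, Obp56e at -3.61, Obp83ef at -3.09, Obp57a at 1.01 and Obp84a at 0.97. The perireceptor genes Ugt35B1 (0.73; 3906 against 2348 CPM) and Cyp49a1 (0.91) were the 2 of 14 that passed (10 over the list alone).

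Outside the chemosensory lists, the detoxification enzyme gene Cyp6a2 was higher in Orco2 and nompA, which links mechanosensory cilia to the cuticle, was lower. At 0 min Cyp6a2 was higher by 2.42 ± 0.15, with Ugt35C1 at -2.07 and Cyp6a13 at 0.94, among 6 of 22 detoxification genes (13 over the list alone). nompA was at -4.15, the only 1 of 14 Johnston's organ genes to pass (3 over the list alone). Of 18 activity-regulated genes, 2 passed (6 over the list alone): CG17778 (-1.22) and Arc1, a retrotransposon-derived capsid gene (1.15). Passing genes elsewhere were Sytbeta (0.74), Irk1 (0.69), Irk3 (-0.88), Ppn (1.28), Sr-CI (1.02), to (0.73), FASN1 (0.68) and Lsp2 (3.28). None passed among heat shock, antimicrobial, phototransduction, circadian, receptor, neuropeptide, oxidative phosphorylation, ribosomal, proteasome, chromatin, glial, glycolysis, muscle or oxidative stress genes (3 glycolysis genes passed over the list alone). The median and the mean differed in sign for the Johnston's organ, synaptic, proteasome, glial, fat body and detoxification lists.

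**Figure D1:**
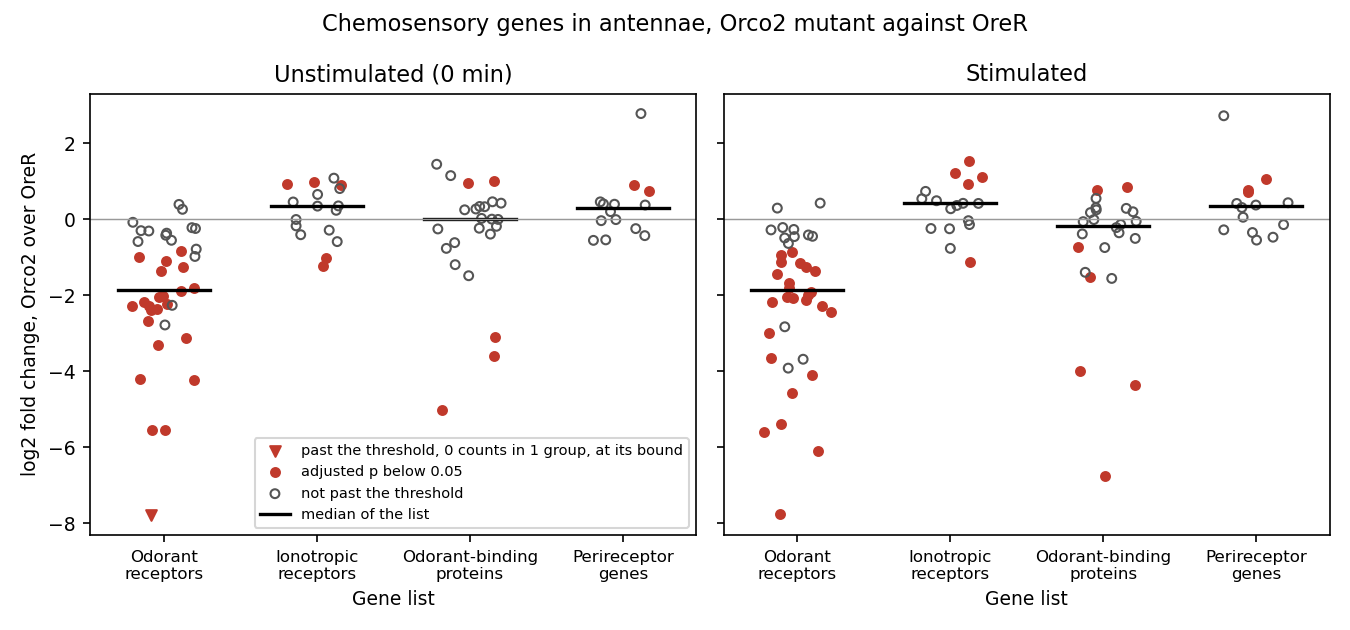
Log2 fold change of Orco2 over OreR antennae for 4 lists of chemosensory genes, at 0 min (left) and after stimulation (right), with red for an adjusted p under 0.05, a triangle for a bound and bars for medians. Odorant receptors lie below 0 in both panels, with medians of -1.85 and -1.86.

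After stimulation the genotypes differed in much the same genes. The 808 genes that passed (468 higher and 340 lower; 2463 at an unadjusted p under 0.05) overlapped those of 0 min in direction without exception, with 279 higher in both where 13.9 would be expected by chance, 224 lower in both where 8.2 would be, and 0 in opposite directions. With the fragment length as a batch term 1487 passed, with DESeq2 1498, with the compared libraries alone 423, and with a library left out 260 (Orco2 C), 267 (Orco2 B), 367 (OreR A) or 542 (OreR B). CG32640 was at least 144-fold and CG31274 at least 141-fold higher (adjusted p = 0.0035 for CG31274), cas was at 9.61, CG30428 at 8.18, ppk27 and Uros2 at 7.15, CG42876 at 7.05, CG6912 at 6.70, Osi3 at 6.63 and CG3984 at 5.81. CG3397 was at least 185-fold lower, sordd2 at -9.42, CG3119 at -8.20, Or46a at -8.05, Or19a at -7.75, CG42766 at -7.36 and Obp99d at -6.74 ± 0.43 (0.365 against 40.2 CPM). E(spl)mgamma-HLH was at -6.60 and CG32301 at -6.56. Of the odorant receptors, 25 were lower (30 over the list alone; median -1.86, camera adjusted p = 2.07e-43, and adjusted p = 0.21 with an estimated correlation).

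Many chemosensory genes that passed at 0 min also passed after stimulation, and some genes of other lists passed there. Whether genes differed between the 2 contrasts is the question of the interaction below. Ir25a (1.10), Ir75b (1.23), Ir75c (1.54) and Ir92a (0.93) were higher and Ir76a (-1.13) lower among 5 ionotropic receptors (11 over the list alone; camera adjusted p = 0.0141, and adjusted p = 0.427 with an estimated correlation). Among 7 odorant-binding protein genes (7 over the list alone), Obp83ef was at -4.37, Obp56e at -4.0, Obp99c at -1.53 and Obp56d at -0.74. In Johnston's organ, nompA was at -4.0 while Dhc93AB (1.44), an axonemal dynein gene, btv (0.69) and wtrw (0.58) were higher, 4 genes in all (11 over the list alone). The antimicrobial peptide gene Drs was at -3.32, the heat shock genes Hsp23 and Hsp27 at -2.53 and -1.08, the glial gene wrapper at 2.01 and the muscle gene TpnC41C at -1.73. Cyp6a2 was at 2.11 (1838 against 344 CPM), Lip4 at -1.0, Pepck1 at -0.91, Ppn at 1.85 and Col4a1, a collagen gene, at 0.80.

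In OreR antennae, hry, which encodes a transcriptional repressor of the hairy family, had the smallest p-value after odor and light, but no gene passed the edgeR test. The next genes were Tdc1, a tyrosine decarboxylase gene, CG31274, Cdc7, a kinase gene of DNA replication, and CG15673. The edgeR quasi-likelihood test called 0 of 11298 genes, with 186 at an unadjusted p under 0.05 where 565 would be expected by chance. DESeq2 called 9 and the fit with the fragment length as a batch term 1, hry among them in both. hry stood at 83.6 ± 1.97 CPM at 0 min and 217 ± 9.88 CPM after stimulation (log2 1.37 ± 0.11; adjusted p = 0.0693). Tdc1 stood at 6.13 and 16.2 CPM (1.40 ± 0.17; adjusted p = 0.45), CG31274 at 2.90 and 0 CPM, Cdc7 at 0.74 ± 0.11 on the log2 scale (adjusted p = 0.644) and CG15673 at 0.91 ± 0.16. The activity-regulated list had a median of 0.04 and did not pass camera (adjusted p = 0.157). The antimicrobial list (median 0.59; camera adjusted p = 8.34e-06) and the hemocyte list (median -0.38; camera adjusted p = 2.13e-07) passed. Neither did with an estimated correlation (adjusted p = 0.416 and 0.311).

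Antennae of Orco2 gave the same leading gene: hry again had the smallest p-value, followed by fon, a gene of hemolymph clotting, Ance-4, sPLA2 and Cyt-b5-r. No gene passed the edgeR test here either (0 of 11298, 241 at an unadjusted p under 0.05), while DESeq2 called 31 (among them hry, fon and cbt) and the fit with the fragment length as a batch term 11 (among them hry and fon). hry stood at 76 ± 8.21 CPM at 0 min and 190 ± 8.42 CPM after stimulation (log2 1.32 ± 0.11; adjusted p = 0.0874). fon stood at 42.6 and 20.0 CPM (-1.09 ± 0.12; adjusted p = 0.253), Ance-4 at -1.20 ± 0.14, sPLA2 at -1.05 and Cyt-b5-r at -1.02. cbt, a zinc finger transcription factor gene of the activity-regulated list, stood at 94.3 ± 6.13 and 151 ± 20.8 CPM (0.68 ± 0.12) and passed over that list alone (adjusted p = 0.014), the only 1 of 18. Pepck1 (-1.03; adjusted p = 0.0203), Xrp1 (0.32) and Lip4 (-0.76) passed over the oxidative stress list alone. Camera called the activity-regulated list (median 0.12; adjusted p = 0.00279), but it had an adjusted p of 0.457 with an estimated correlation.

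**Figure D2:**
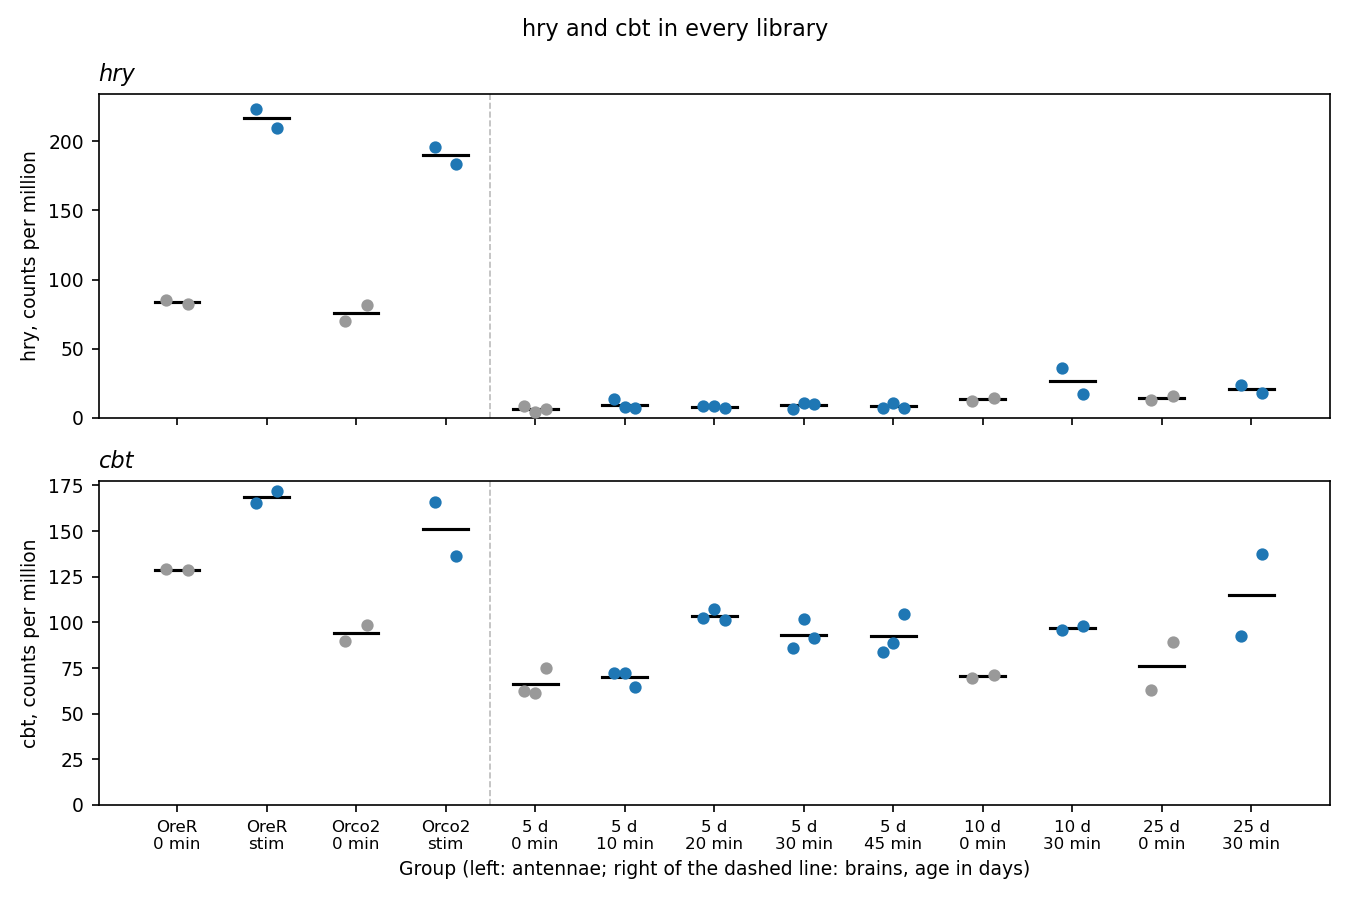
Level of hry and cbt (CPM) in each library of the 13 groups, with lines at the group means. In antennae hry lies at 83.6 and 76 CPM at 0 min and at 217 and 190 CPM after stimulation.

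The leading genes of the test for a difference between the responses of the 2 genotypes were fon and CG2233. The interaction called 0 of 11298 genes by edgeR (316 at an unadjusted p under 0.05), DESeq2 called 30, among them both of these, and the fit with the fragment length as a batch term 1, CG2233. The smallest p-values belonged to fon (-1.65 ± 0.17; adjusted p = 0.387), CG2233 (-1.53 ± 0.18; adjusted p = 0.471), Cyt-b5-r (-1.39; adjusted p = 0.54), CG15293 (-1.86) and CG31274. The antimicrobial list had a median of -0.86 (camera adjusted p = 1.99e-05), and an adjusted p of 0.476 with an estimated correlation. Across all genes the response of Orco2 and that of OreR had a correlation of -0.30, which ranged from -0.60 without OreR stimulated A to 0.30 without OreR stimulated B. The 2 genotype contrasts, at 0 min and after stimulation, had a correlation of 0.48 (0.14 without OreR stimulated A) and one of 0.96 over the 911 genes called in either.

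In brains of 5-day flies, cbt, a gene of the activity-regulated list, was higher at 20 min, where it passed over its list alone but not over all genes. EloC, the elongin C gene, btv, daw, an activin-type ligand gene, and Spn88Eb, a serpin gene, were among those with the smallest p-values. By edgeR 0 of 10431 genes passed at 10, 20, 30 or 45 min or in the joint test of any time, with 204, 93, 229, 181 and 182 at an unadjusted p under 0.05 where 522 would be expected by chance. DESeq2 called 11, 16, 16, 16 and 4. Most of its calls at single times had log2 folds of implausible size, such as 28.12 for LysD and 28.64 for CG6295 at 20 min. These counts are therefore not read as a response. cbt stood at 66.2 ± 7.56 CPM at 0 min, 104 ± 3.05 at 20 min (log2 0.65 ± 0.15; adjusted p = 1, and adjusted p = 0.00857 over the list alone), 93.1 ± 8.12 at 30 min (0.49 ± 0.15; adjusted p = 0.879) and 92.4 ± 11 at 45 min. Spn88Eb was at -2.43, -2.90 and -3.35 at 10, 20 and 45 min from 5.85 ± 6.46 CPM at 0 min, where its control libraries spread widely. EloC was at 0.49 ± 0.13 at 30 min and 0.44 at 45 min, daw at 0.60 ± 0.17 and btv at -0.70 ± 0.18 at 30 min, and Cdc7 at 0.63 ± 0.16 and CG44195 at -0.71 at 45 min. AttC, an attacin gene, was at -3.31, -3.25 and -3.23 at 20, 30 and 45 min, and antimicrobial genes passed over that list alone in 2, 4 and 2 cases.

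At 10 min the muscle list stood out through 1 library. Its median was 1.86, with 10 of 18 genes passing over the list alone, among them Act88F (3.72), a flight muscle actin gene, and TpnC41C (4.03), a troponin gene. Camera gave an adjusted p of 5.14e-17, and an adjusted p of 0.473 with an estimated correlation. The 10 min library A lay 2.98 above the mean of the brain libraries in this list, so muscle in that dissection is a ready account, and it was not tested further. The ribosomal protein list had medians of 0.49, 0.32, 0.69 and 0.62 at 10, 20, 30 and 45 min (camera adjusted p from 4.88e-17 to 5.93e-08; adjusted p of 0.529 to 0.643 with an estimated correlation). The 0 min library C, shared by these contrasts, was itself low in this list (-1.17 against the mean of brain libraries). Without it and the other low libraries the medians of cytosolic ribosomal proteins were 0.26, 0.08, 0.41 and 0.35. The 0 min library B, also below that mean but less so, stayed in these fits. The activity-regulated list had medians of 0.08, 0.23 and 0.26 at 20, 30 and 45 min (camera adjusted p = 0.000604, 0.000266 and 2.91e-07; adjusted p = 0.448, 0.529 and 0.545 with an estimated correlation).

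**Figure D3:**
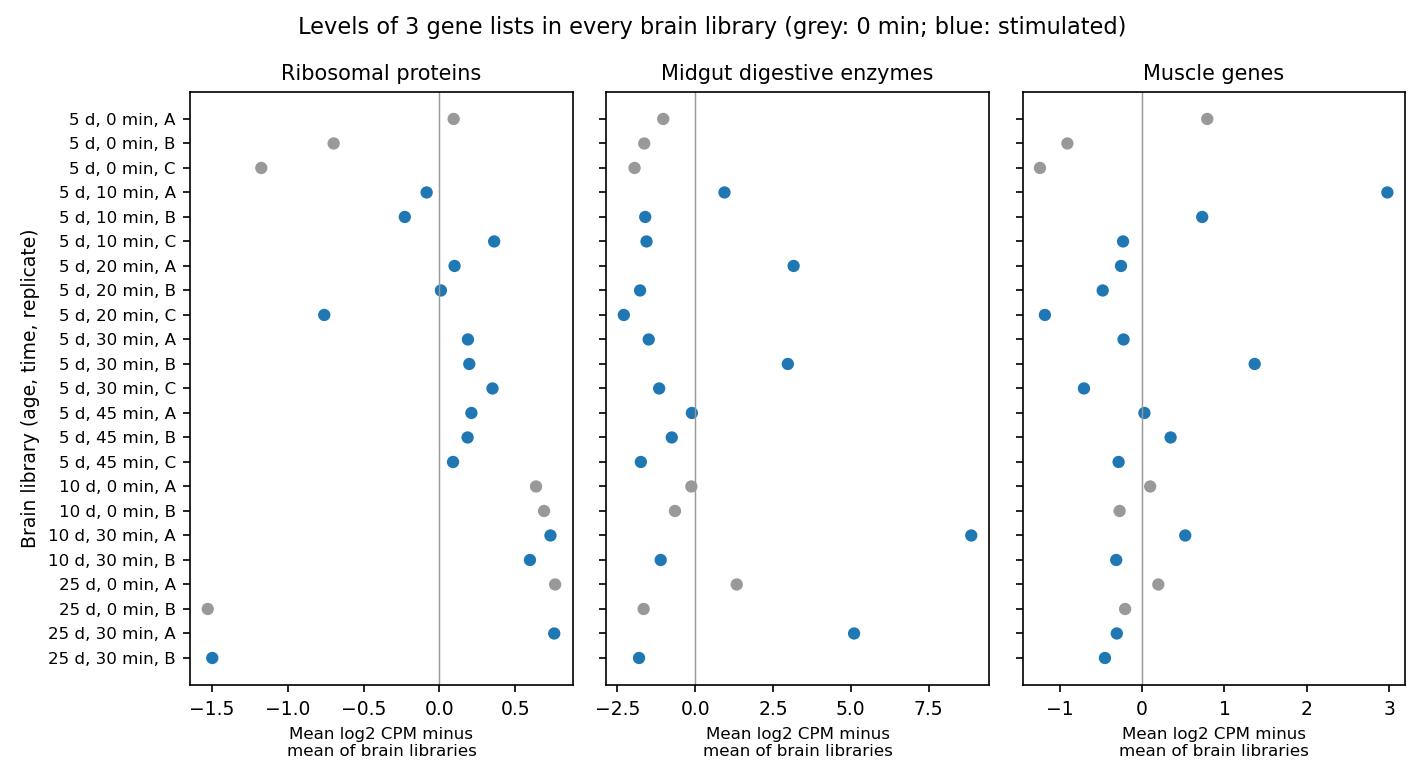
Mean log2 CPM of the ribosomal, midgut enzyme and muscle lists in each of the 23 brain libraries, minus the mean of all brain libraries. The 10-day 30 min library A lies 8.87 above in midgut enzymes, and 5-day 0 min C lies 1.17 below in ribosomal proteins.

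In older brains no gene passed the edgeR test after odor and light for 30 min, while DESeq2 called 121 at 10 days and 1 at 25 days. The latter was CG4377, at an implausible log2 fold of 19.99. At 10 days, genes with the smallest p-values were Bace, a beta-secretase gene, CG31288, Mal-A2, a maltase gene, CG5107 and CG43055, all carried by 1 library. edgeR called 0 of 10431 genes (335 at an unadjusted p under 0.05) and 1 with the fragment length as a batch term. Without 30 min B genes passed, but these rest on library A alone at 30 min. Bace stood at 462 ± 653 CPM at 30 min and 0.207 at 0 min (11.08 ± 2.20; adjusted p = 0.262). The neuropeptide list had a median of -0.24 (camera adjusted p = 0.000228; adjusted p = 0.375 with an estimated correlation). At 25 days edgeR again called 0 (75 at an unadjusted p under 0.05), with CG10663 (-1.07 ± 0.26), GIIIspla2 (-0.60 ± 0.18), a phospholipase gene, cbt (0.59 ± 0.18; 76.2 ± 18.6 and 115 ± 31.7 CPM), Cyp4g1 (-5.83) and Faa (-2.67) first, all at an adjusted p = 1. The phototransduction list had a median of -0.50 (camera adjusted p = 2.36e-09; adjusted p = 0.212 with an estimated correlation).

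The edgeR interaction tests called no gene for a difference between ages, and DESeq2 called some. Genes with the smallest p-values included the digestive enzyme gene tobi and CG5107 for 10 against 5 days, Cyp4g1 and TotC, a stress-induced gene, for 25 against 5 days, and Akh, the adipokinetic hormone gene, for 25 against 10 days. edgeR called 0 of 10431 genes in each (322, 79 and 149 at an unadjusted p under 0.05), and DESeq2 called 27, 7 and 5. All 7 for 25 against 5 days had log2 folds of implausible size, such as LysD at -26.77 and Cht4 at -23.52. The 5 for 25 against 10 days included Bace, tobi and CG5107. Without the 10-day 30 min library B, genes passed for 10 against 5 days and for 25 against 10 days, but these rest on library A alone in that group. tobi, CG5107 and CG31104 followed the 10-day 30 min library A, which stood out in midgut enzymes (8.87 above the mean of brain libraries). Without the libraries marked by gut or muscle genes, tobi fell from 8.18 to 0.65 and CG31104 from 5.94 to 1.15. That fit dropped library A for its gut genes and left 1 library (B) at 10 days and 30 min. The fall was therefore built into the choice of libraries and tests no cause. TotC was at -6.64, fusl at -0.78, Adck1 at 0.70, Akh at 3.02 ± 0.79 and Mdr50 at -4.26. Across genes the responses had correlations of 0.12 (5 and 10 days), 0.13 (5 and 25 days) and 0.33 (10 and 25 days), which fell to -0.24 without 10-day 30 min A and to -0.65 and -0.19 without 25-day 30 min A.

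Brains of 10-day and 5-day flies at 0 min differed in a few genes, in calls that rest on single libraries. The neuropeptide genes Crz (corazonin), Orcokinin and Mip (myoinhibiting peptide) rose, as did EloC and IscU, a scaffold gene for iron-sulfur clusters. Cda5, a chitin deacetylase gene, tyn, mbc and kcc, a potassium chloride cotransporter gene, fell. edgeR called 12 of 10431 genes (5 higher and 7 lower), with 1755 at an unadjusted p under 0.05. The number depended on the fit: 6 with the fragment length as a batch term, 552 with DESeq2, 5186 with voom and 1410 with a replicate block whose letters were shared between ages. It was 700 without libraries low in ribosomal protein genes, and 0 with the compared libraries alone or without those marked by gut or muscle genes. All of the marked libraries were stimulated ones, so leaving them out kept every compared library and changed only the shared fit. CG10177 and Or10a were among the 6 of the batch term. Crz, Orcokinin, Mip, EloC, IscU, Cda5, tyn, mbc and kcc were not. No gene passed without 5-day B, 5-day C, 10-day A or 10-day B (0 in each case), and 16 passed without 5-day A. Crz stood at 108 ± 3.64 against 40.7 ± 3.30 CPM (1.41 ± 0.26; adjusted p = 0.0496), Orcokinin at 168 ± 2.71 against 63.7 ± 11.2 (1.40 ± 0.25; adjusted p = 0.0458) and Mip at 209 ± 17.1 against 82.7 ± 17.7 (1.34 ± 0.22; adjusted p = 0.0227). EloC was at 0.89 ± 0.14, IscU at 0.71 ± 0.13, CG10177 at -1.72 ± 0.32, Cda5 at -1.56 ± 0.26, tyn at -1.33 ± 0.20, mbc at -0.84 ± 0.14, kcc at -0.77 ± 0.14 and Or10a at -1.58.

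Of 27 genes of the neuropeptide list, which does not hold Orcokinin, Crz and Mip passed (13 over the list alone), with a median of 0.76 (camera adjusted p = 9.52e-11; adjusted p = 0.117 with an estimated correlation; fry adjusted p = 0.00288). Synaptic vesicle genes had a median of -0.54, with 0 passing over all genes and 12 over the list alone, among them Gad1 (-0.77 ± 0.17), which makes GABA, VGAT (-0.48), shi (-0.61) and comt (-0.42). Camera gave an adjusted p of 1.6e-12, and an adjusted p of 0.31 with an estimated correlation. Ion channel genes passed in 10 cases over the list alone and 0 over all genes, with Irk1 at 0.94 and NaCP60E at -1.14. Ribosomal protein genes had a median of 1.09 (5 over the list alone, 0 over all genes; camera adjusted p = 1.64e-15, and adjusted p = 0.373 with an estimated correlation). The 5-day control library C was low in this list (-1.17), and without the low libraries the median of cytosolic ribosomal proteins was 0.84. The 5-day control library B, also below the mean of brain libraries but above the limit of -1, stayed in that fit. Gene length moved with this contrast: genes under 800 bases relative to genes over 3000 bases lay at 0.559 and 0.39 (log2) in the 10-day libraries and at -0.435, -0.512 and 0.012 in the 5-day ones. Relative to genes of matched length the medians were 0.39 for neuropeptides, -0.36 for synaptic vesicles, -0.13 for ion channels and 0.72 for ribosomal proteins, so length may carry part of these shifts, and these differences were not tested. The chromatin list had 3 over the list alone (G9a at -0.78, HDAC1 at 0.48) and the glial list 5 (Eaat1 at -0.92, wrapper at 0.82), with 0 over all genes in both.

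**Figure D4:**
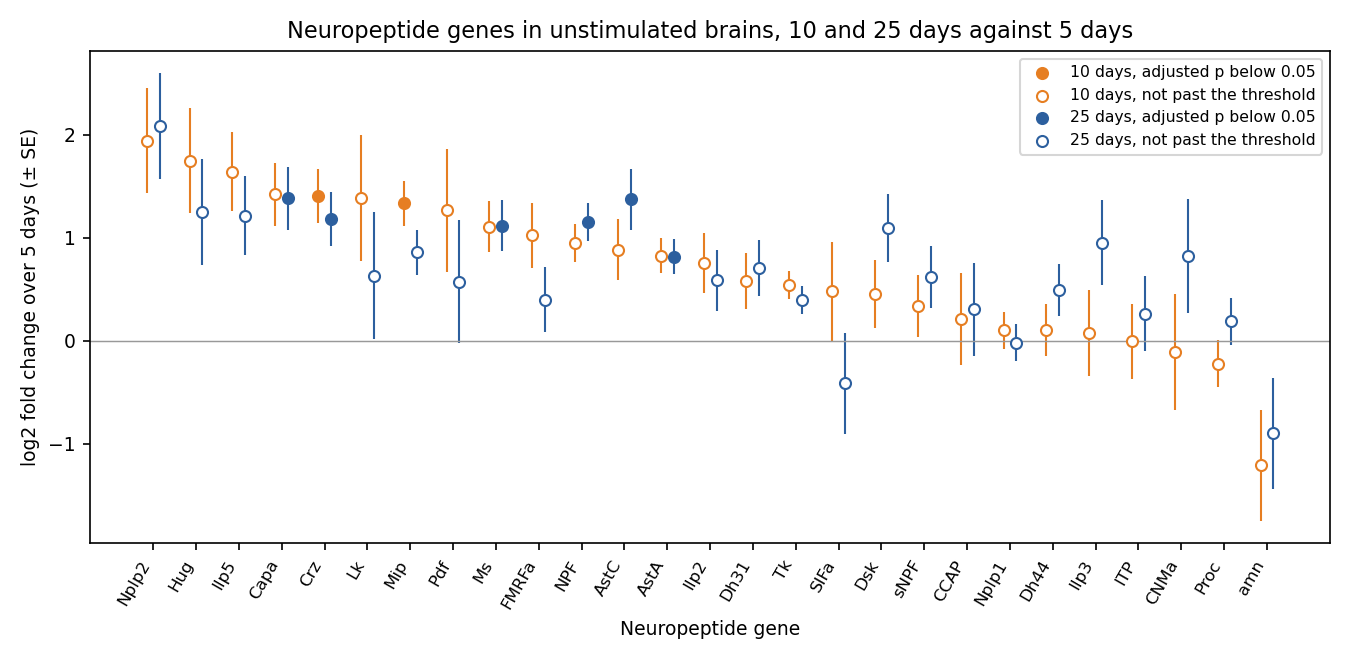
Log2 fold change (± SE) of neuropeptide genes in brains at 0 min, for 10 and 25 days against 5 days. Medians lie at 0.76 and 0.71.

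Brain libraries of 25-day flies at 0 min held more transcripts of NimC1, a phagocytosis receptor gene of hemocytes, and of the neuropeptide gene NPF than those of 5-day flies. They held fewer transcripts of Eaat1, the glial glutamate transporter gene. lectin-28C and MtnA, a metallothionein gene, also rose, and the small heat shock gene Hsp67Bc and comt, the NSF gene of vesicle fusion, fell. edgeR called 172 of 10431 genes (108 higher and 64 lower; 1653 at an unadjusted p under 0.05), 61 with the fragment length as a batch term, 543 with DESeq2, 0 with voom and 0 with the compared libraries alone. 25-day B and 5-day C, on the 2 sides of this contrast, were low in ribosomal protein genes (-1.53 and -1.17 against the mean of brain libraries). A fit without the low libraries leaves 25-day A alone at 25 days, so it does not test whether these calls hold. Without 5-day A 42 passed, without 5-day C 137 and without 5-day B 0. Leaving out 25-day A or 25-day B changed the calls strongly, but left 1 library at 25 days. CG12256 was at 5.12 ± 1.0 (149 ± 71.0 against 4.26 CPM; adjusted p = 0.0236), CG4250 at 2.81, lectin-28C at 2.78 ± 0.63, NtR at 2.73, CG44014 at 2.71, NimC1 at 2.68 ± 0.48 (27.1 ± 2.72 against 4.19 ± 2.35 CPM; adjusted p = 0.0179), CG4950 at 2.56, mthl2 at 2.53, Muc14A at 2.48 and CG4716 at 2.43. Lower genes were CG10185 (-1.86), CG10177 (-1.69), CG8568 (-1.68), Cda5 (-1.29), Hsp67Bc (-1.28 ± 0.25), tyn (-1.26), TM4SF (-1.11), obst-A (-1.08), Eaat1 (-1.02 ± 0.19; 587 ± 64.1 against 1186 ± 190 CPM), CG14434 (-0.90) and comt (-0.71 ± 0.13).

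Neuropeptide genes passed in 6 cases (12 over the list alone; median 0.71, camera adjusted p = 3.84e-11, adjusted p = 0.0822 with an estimated correlation, fry adjusted p = 0.004). NPF stood at 68.6 ± 9.26 against 30.7 ± 4.44 CPM (1.16 ± 0.19; adjusted p = 0.0179), with AstC at 1.38, Capa at 1.39, Crz at 1.19, Ms at 1.12 and AstA at 0.82. Hemocyte genes had a median of 1.39 with 2 passing (5 over the list alone; camera adjusted p = 0.00195, and adjusted p = 0.111 with an estimated correlation), among them Sr-CI (2.15). Camera also called the phototransduction list (median 1.40; adjusted p = 0.000252) and the antimicrobial list (median 1.59; adjusted p = 0.000146), each with an adjusted p of 0.368 with an estimated correlation. The fat body list (median 0.67) did not pass (camera adjusted p = 0.0543). The hemocyte and fat body lists were written as lists of other cell types, and the phototransduction list also as one of retina. Whether their shifts, and those of NimC1 and Sr-CI, reflect such cells in the dissection was not tested. Relative to genes of matched length the medians were 0.55 for neuropeptides, 1.74 for hemocytes, 1.32 for phototransduction and 1.04 for antimicrobial genes. In the oxidative stress list MtnA (1.25 ± 0.23; 254 against 107 CPM) passed (3 over the list alone). The circadian list had a median of -0.03 and a mean of 0.07, with vri (0.97) passing over the list alone and 0 over all genes. Between 25 and 10 days edgeR called 0 of 10431 genes (342 at an unadjusted p under 0.05) and DESeq2 3. Without 25-day A many genes passed, but these rest on 25-day B alone. First in the full fit were path (0.77 ± 0.17), FASN3 (1.99), CG13794 (1.33), ttk (0.65) and CG6701 (0.62), all at an adjusted p = 0.637. The fold changes at 10 and 25 days against 5 days had a correlation of 0.60 where simulated unchanged groups with the same controls gave 0.41, and 0.11 without 25-day A. The simulation held no shift shared by many genes of 1 library, so the gap does not show a shared effect of age. The responses of 5-day brains at 30 and 45 min, with 0 genes called, had a correlation of 0.81 against a simulated 0.50.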

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

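The fit with the fragment length as a batch term, which picked out the gene below, was chosen after the data were seen, while the replicate block and DESeq2 were planned. CG2233, a gene of undescribed function on chromosome X (8035741 to 8037517), had a different response in the antennae of the 2 genotypes by that fit of the interaction. Its level in Orco2 antennae was 321 ± 15.3 CPM at 0 min and 164 ± 0.0643 CPM after stimulation (SD, n = 2), against 319 ± 41.1 and 470 ± 56.5 CPM in OreR. The interaction was -1.53 ± 0.18 on the log2 scale. Within each antennal genotype the fragment length and the replicate letter part the libraries in the same way, so the planned replicate block gave the same values as the batch term. By the edgeR quasi-likelihood test the adjusted p was 0.471 with neither term and 0.00863 with either, and over all alternatives it ran from 1.8e-09 (DESeq2) to 1 (without Orco2 stimulated B or C). No biological explanation was tested.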

How the results depend on the processing

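The fragment-length batch, the surrogate variables, voom with sample quality weights, the effects averaged over groups, the comparison with genes of matched length, the replicate block for the genotype contrasts and the fits without libraries that stood apart were chosen after seeing the data. The rule for libraries that stand apart first took 8 libraries as 1 set, and they were parted into 2 sets after that was seen. Scaling by DESeq2 size factors or from TPM changed few counts, whereas the tool, the batch term, surrogate variables and single libraries changed many. With 2 libraries per group, letters gave correlations of deviations of 0.73 (OreR), 0.02 (Orco2), -0.2 (10 days) and 0.88 (25 days). Among 5-day brains same-letter values ran from -0.36 to 0.74, and among C libraries alone from 0.4 to 0.74. The C libraries were also deeper (42.2 to 62.0 M against 19.3 to 29.5 M in A and B). Not every library correlated best with its own letter, so letters were not taken as pairs in the main fit. The block is given here and for CG2233. Within antennae and older brains letters part the libraries by fragment length. The main fit leaves that difference in its spread and may miss changes. For stimulation the block took letters within each genotype or age. The genotypes share only letter B (354 bases in OreR and 298 in Orco2), which alone connects the block of the genotype contrasts. In the age contrasts at 0 min the block took letters as shared between ages. There, libraries A had 369 bases at 5 days and 325 at 10 and 25 days, and libraries B 369 and 335. The blocks of the genotype and age contrasts therefore equate libraries of unlike fragment length. With both sets left out no 25-day library at 30 min remained. Without low-ribosomal libraries 1 library (A) was left in each 25-day group. Without gut- or muscle-marked libraries 1 (B) was left at 30 min at 10 and at 25 days. Counts from comparisons of such groups, and from leaving out 1 of 2 libraries of a group, rest on single libraries. The gut- or muscle-marked libraries were all stimulated ones. Leaving them out of the age contrasts at 0 min therefore kept every compared library and changed only the shared fit.

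For stimulation of OreR antennae (0 genes), 1 passed without a filter, 1 with the replicate block, 1 with the fragment-length batch, 1, 3 and 31 with 1, 2 and 3 surrogate variables, 18 with voom weights and replicate block and 9 with DESeq2. For Orco2 (0), 11 passed with the replicate block, 11 with the batch, 3, 45 and 95 with surrogate variables, 1 with voom, 60 with voom and replicate block and 31 with DESeq2. For the interaction (0), 1 passed with the replicate block, 1 with the batch, 26 and 62 with 2 and 3 surrogate variables, 48 with voom and replicate block and 30 with DESeq2. With each library left out all 3 stayed at 0. In antennae the batch parts the libraries of a genotype as the letters do, so these fits gave the same counts for stimulation. hry was among the genes called with the replicate block, the batch, each number of surrogate variables, voom with replicate block and DESeq2 in both genotypes, and its adjusted p ran from 2.53e-26 to 1 in OreR and from 6.9e-24 to 1 in Orco2, with a log2 fold of 1.136 to 1.471. For Orco2 against OreR at 0 min (606), 2282 passed with the replicate block (592 of them among the 606, and 44.7% higher), 1141 with the batch, 1322 and 23 with 2 and 3 surrogate variables, 311 with the compared libraries alone, 1093 with DESeq2 and 264 to 286 with a library left out. After stimulation (808), 2027 passed with the replicate block (775 of them among the 808), 1487 with the batch, 1438, 2461 and 17 with 1, 2 and 3 surrogate variables, 423 with the compared libraries alone, 1498 with DESeq2 and 260 to 542 with a library left out.

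For 5-day brains at 10, 20, 30 and 45 min and any time (0 each), voom gave 1614, 3578, 3503, 3484 and 2977, voom with replicate block 1332, 2773, 3200, 2851 and 1989, and DESeq2 11, 16, 16, 16 and 4. The voom weights of brain libraries ran from 0.12 to 7.1. Voom without weights was not run, so what raised these counts is open. At 20 min 1 gene (cbt) passed without low-ribosomal libraries. For 10 days at 30 min (0), 5 passed with the replicate block, 2 with the crossed replicate block, 1 with the batch, 344 with voom and replicate block, 121 with DESeq2 and 0 to 246 with a library left out. For 25 days at 30 min (0), 3 passed with voom and replicate block and 1 with DESeq2. For the interaction of 10 and 5 days (0), 308 passed with voom, 556 with voom and replicate block, 1 with the compared libraries alone (Akh), 27 with DESeq2 and 0 to 108 with a library left out. For 25 and 5 days (0) 7 passed with DESeq2, and for 25 and 10 days (0) 56 with voom and replicate block, 5 with DESeq2 and 0 to 67 with a library left out. The replicate block changed no other call in stimulated brains.

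For 10 against 5 days at 0 min (12), 27 passed with DESeq2 size factors (29.6% higher in place of 41.7%), 4 without a filter, 1410 with the replicate block, 6 with the batch, 806 and 634 with 2 and 3 surrogate variables, 5186 with voom, 0 with the compared libraries alone, 552 with DESeq2, 700 without low-ribosomal libraries, 0 without gut- or muscle-marked libraries, 0 without both and 0 to 16 with a library left out. For 25 against 5 days (172), 94 passed without a filter, 85 with counts scaled from TPM (50.6% higher in place of 62.8%), 1575 with the replicate block, 61 with the batch, 358 with 3 surrogate variables, 0 with voom, 0 with the compared libraries alone, 543 with DESeq2, 51 without gut- or muscle-marked libraries (88.2% higher), 60 without both and 0 to 1165 with a library left out. Without low-ribosomal libraries only 25-day A was left at 25 days, so the calls of that fit are not read. For 25 against 10 days (0), 3 passed with DESeq2, 17 without both sets and 0 to 2430 with a library left out; without low-ribosomal libraries the synaptic list reversed to -0.136 and the ribosomal list to 0.085.

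Of the gene list tests, 157 were called by camera at the preset correlation, 0 with an estimated correlation and 11 by fry. With 3 surrogate variables, genes reversed between genotypes at 0 min (CG30428 -8.708, Or19a 0.313, CG42766 0.359, CG17778 0.388, Obp83ef 2.919) and after stimulation (CG30428 -6.672, CG42876 -2.629, Or19a 17.141, CG32301 2.944, CG17778 0.672, Or67b 0.009, Obp83ef 2.607, Gr21a -0.492, Hsp27 0.27, wrapper -4.221, Col4a1 -0.797). The correlation of the genotype contrasts was 0.48 over all genes and 0.96 over genes called in either. With each library left out it ran from 0.14 to 0.64, that of the OreR and Orco2 responses from -0.6 to 0.3, of 5 and 10 days from -0.24 to 0.25, of 5 and 25 days from -0.65 to 0.63, of 10 and 25 days from -0.19 to 0.42 and of the ages at 0 min from 0.11 to 0.77.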

Other observations

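The tests below were chosen after the result they examine was seen; for the genes near Orco and for the regrouped libraries, the criterion was written before the value of that test was computed. What the tests of the odorant receptor list, the enzyme response, short transcripts, the fragment-length batch, age and the joint regrouping were taken to show was altered after values were seen. The 606 genes that differed between Orco2 and OreR antennae at 0 min could come from the mutation or from the strain. A variant carried along with the mutation was tested first: genes within 5 Mb of Orco passed no more often than others (38 of 664, 5.72% against 5.34%; odds ratio 1.08, Fisher's exact p = 0.657), so linkage near Orco was excluded as the source of the whole set, although it may still account for single genes such as cas, which lies near Orco on 3R. No testis gene passed (0 of 17), so testis RNA in both libraries of 1 genotype is an unlikely source of the whole set. Testis RNA in single libraries was not excluded, because with 2 libraries per group it need not pass this test. The lower odorant receptor list (median -1.85) is part of the pattern itself, so it does not test whether loss of Orco lowered these transcripts, and that remains open. Strain background across the genome also remains open, and 571 of the genes lay outside the chemosensory lists.

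Digestive enzyme genes were highest in 10-day 30 min A (8.87 above the mean of brain libraries, log2) and also stood out in 25-day 30 min A (5.10), 5-day 20 min A (3.16) and 5-day 30 min B (2.98), which may reflect midgut tissue in the dissection. The 10 midgut genes tested outside the digestive enzyme list lay 6.54 higher (log2, median) in 10-day 30 min A than in the other brain libraries, which fits that explanation. They include the lysozyme genes LysB, LysD, LysE and LysP and the chitinase gene Cht4, which encode enzymes too. Of the 10, 6 lay above the highest other library. A response to odor and light remains open: in the other 10-day library at 30 min the enzyme list lay at -0.458 relative to the lower 0 min library, but that sets 1 library against 1, and all 4 libraries named here are stimulated ones.

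Ribosomal protein genes were low in 25-day 0 min B (-1.53), 25-day 30 min B (-1.50) and 5-day 0 min C (-1.17, log2 against the mean of brain libraries), which could reflect RNA handling or library preparation. Loss of short transcripts remains open. The difference between genes under 800 and over 3000 bases was -0.101, -0.006 and 0.012 in these libraries. That is lower than in 25-day A at 0 and 30 min (0.477 and 0.495) but higher than in 5-day 20 min A and B (-0.482 and -0.491), where ribosomal protein genes were not low (0.1 and 0.01). The fragment-length batch was excluded as the whole cause, as the other 10 libraries of that fragment length averaged 0.211 (SD 0.391) and the lowest of them, 5-day 20 min C, lay at -0.759, above the 3 libraries. Age remains open: 25-day A lay at 0.763 at 0 min and 25-day B at -1.53, and 1 of the 3 libraries was of 5-day flies.

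hry might respond to odor and light in both genotypes. Averaged over both, it was higher by 1.35 ± 0.08 (adjusted p = 0.00791, edgeR quasi-likelihood test), with 4 of 4 stimulated libraries above every control. This was 1 of 4 averages tried, and the other 3, in brains, called 0 genes. In the brain average of 5 days at 20 and 30 min with 10 and 25 days at 30 min, cbt had the smallest p. There it was higher by 0.55 ± 0.09 (adjusted p = 0.186, edgeR quasi-likelihood test), with 10 of 10 stimulated libraries above every control of their age. Only the antennal average called a gene, hry. The call held without Orco2 0 min C (adjusted p = 0.0417) and was lost without any of the other 7 libraries (adjusted p from 0.0609 to 0.107, the last without Orco2 stimulated B), while the log2 fold stayed at 1.29 to 1.37 in these fits. A direct test would be quantitative PCR of hry in new antennae of both genotypes at 10, 20 and 30 min.

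A rise of activity-regulated genes in 5-day brains remains open. The list mean gave an exact permutation p of 0.0818 for 0 min against 20, 30 and 45 min. Without 5-day 0 min A it gave 0.0182, the smallest possible. That library was the control highest in Hr38 (124.64 against 20.43 and 13.52 CPM) and sr (81.17 against 40.81 and 30.35 CPM). Leaving it out favors a rise, so the smaller p is no support, and 0 min B and C were not left out in turn. The test also takes libraries as alike, though in A and B the fragment length differed between 0 and 20 min and 30 and 45 min. CG13055 (difference 0.57) and cbt (0.54) each gave an exact p of 0.00455, the smallest possible (adjusted p = 0.0409 over 18 genes by the Benjamini-Hochberg method). Hr38 (1.12) and sr (0.69) gave an exact permutation p of 0.268 and 0.177. At 45 min libraries A, B and C stood at 171.15, 196.8 and 84.15 CPM in Hr38 and at 109.45, 135.21 and 58.12 CPM in sr. Of these, C lay below 0 min A in both genes. Splits of 3 against 3 libraries are too few (10) for a share under 0.05. At 20 min 1 other split (0 min A, 20 min A and 20 min B against the rest) called 71 genes where the real one called 0, which points to a structure of the samples whose cause was not tested, and at 10, 30 and 45 min the highest other split called 0. In the joint test the real split called 0 genes and the highest other 9. As the real count is 0, all 40 splits reach it by definition, and the comparison decides nothing.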
